A study of Mus musculus with 18 samples.

How the data were processed

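RNA sequencing was done on naive CD4 T cells sorted from mixed bone marrow chimeras, 12 weeks after a 1:1 transfer of the studied marrow with CD45.1 WT marrow. RNA was extracted with Trizol, selected for polyA and made into stranded libraries. The deposited values are expected counts per gene, per the labels made with STAR and RSEM on mm10, for which the labels give no versions. The deposited table held 55573 genes and 92 spike-in controls, which were all 0 and were not used. Of the positive values, 3.7% were not whole numbers. Gene coordinates were taken from GENCODE release M21 on GRCm38, the same build as mm10. Identifiers matched for 55394 genes, 55094 of them with the version number, and 179 did not match.

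All 18 libraries were used, grouped by genotype (WT, KO) and condition (unstimulated, weak, strong) as the labels give them, with 3 libraries per group. Totals ran from 33708769 to 64817026 expected counts per library. A count of 0 allows a level of up to 3 counts of a library's total, which is 0.0583 to 0.089 CPM in the unstimulated WT libraries. Such floors cover counting error only. The common dispersion was 0.016, a biological coefficient of variation of 12.6%. TMM factors ran from 0.913 to 1.064.

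Counts were rounded, filtered with filterByExpr by group, scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with 1 coefficient per group and quasi-likelihood tests. The filter kept 15682 genes, which held 99.98% of the counts, and removed 39891. The 13 comparisons were KO against WT in each condition and over the mean of the 3 conditions, each pair of conditions within each genotype, and the KO minus WT difference of each of these responses. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The SE of a log2 change comes from the same fit. CPM values used the TMM-scaled library sizes, and log2 CPM used a prior count of 2.

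The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The named genes were Slc23a2, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in a compared group and no overlap between the groups' libraries. The condition on overlap was not applied to the mean of 3 conditions or to differences in response. In each list the 4 members with the smallest adjusted p followed. Predicted genes, pseudogenes and receptor gene segments were counted but not named. Some genes that the rule names are not reported here. Genes with 3 or fewer counts in every library of a compared group were left out of the folds in the report, and the closing section gives a fitted difference for 1 of them, Spry4, with that limit. Levels of a named gene are given also in conditions other than the one that named it, and Il2, Egr1, Egr2, Nr4a1, Ccr7 and S1pr1 are list members whose levels are given in all conditions.

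The 30 gene lists held 628 distinct genes, of which 608 were tested and 1, Ero1a, was not found under that symbol. They covered immediate early transcription factors, activation receptors and ligands, cytokines and chemokines, ERK and calcineurin feedback, NF-kB feedback, inhibitory receptors and tolerance factors, naive state, helper lineage regulators, regulatory T cell markers and memory and effector markers. Metabolic and stress lists covered glycolysis, hypoxia inducible factor targets, ribosome biogenesis, amino acid transport and folate-linked metabolism, the integrated stress response, cholesterol biosynthesis, NRF2 targets, ascorbate transport and DNA methylation, and JmjC and related dioxygenases. The others were interferon-stimulated genes, apoptosis and p53 targets, cell cycle, proximal T cell receptor signalling, markers of B cells, myeloid and dendritic cells, CD8 T and NK cells and erythroid cells and platelets, heat shock, mitochondrially encoded and sex-linked transcripts. Lists were tested with camera (limma 3.58.1) on voom values at a preset correlation of 0.01, adjusted over the lists within a comparison. At that setting the numbers of lists called in the 13 comparisons, in the order above, were 9, 15, 11, 17, 13, 14, 12, 11, 12, 9, 7, 10 and 10. With an estimated correlation 0 were called in each. This includes strong against no stimulation in WT, where 11269 genes were called. Lack of a call at that setting is thus no evidence that a list was unchanged. For the mean of 3 conditions and for the stimulation comparisons within a genotype, only part of the called lists is described below.

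The response sizes were tested with camera on sets of genes whose mean response over both genotypes was called and at least 1 on the log2 scale. The activation score was tested with exact 2-sided permutations. Same-numbered libraries were checked for pairing by correlating their deviations from group means across genes. The r values exceeded 0.1 in all 9 KO pairs, so KO libraries were treated as paired by number in the blocked fits given beside the KO stimulation results and the differences in response. Pairs of KO replicates 1 and 2 from different conditions also exceeded 0.1, at lower values. The cutoff alone thus cannot tell pairing from KO replicate 3 being unlike the others. Lists of neutrophil, globin, aminoacyl-tRNA synthetase and ribosomal protein genes were added after the data were seen.

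The alternatives were DESeq2 size factors in edgeR, library size alone, voom, DESeq2 1.42.0, no filter, a filter of 5 CPM in at least 3 libraries, fits of 2 groups at a time, replicate blocks, leaving out each library in turn, an estimated correlation, fry, a prior count of 0.5 and response sets of at least 2 on the log2 scale. Fits with KO replicates 1 and 2 alone, KO replicate 3 alone and a block within KO alone were added after the data were seen. The pipeline was tested on simulated counts. edgeR called 71% of 100 genes simulated with a KO against WT log2 change of 1 after weak stimulation and 92% at 2. Among genes simulated without a change it called 7. For the difference in response to weak stimulation it called 57% and 82%, with 7 false genes. The simulated libraries were independent, with no stimulation effect, no pairing and no unlike KO replicate 3. These rates may thus not carry over to the real libraries.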

Results

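RNA was measured in naive CD4 T cells of 2 genotypes, sorted from the spleen and lymph nodes of mixed bone marrow chimeras. WT here denotes cells with the floxed Slc23a2 gene and no Cre, and KO denotes cells with the floxed gene and Cd4Cre, which deletes it in the T cell lineage. Slc23a2 encodes a sodium-dependent transporter of ascorbate, vitamin C, which is a cofactor of the TET enzymes that oxidise methylated cytosine. The sorted cells were kept for 3 h without stimulation or with a weak or strong antibody stimulation of CD3 and CD28, part of the T cell receptor complex and a costimulatory receptor. Each of the 6 groups held 3 libraries, 18 in all. The expected counts summed to between 33708769 (unstimulated WT replicate 3) and 64817026 (weakly stimulated WT replicate 1) per library. Mitochondrial transcripts took 2.27% to 3.16% of a library's counts, and the 10 most abundant genes took 5.14% to 6.33%. Of 55573 genes, 15682 passed the expression filter and were tested. Values below are counts per 1000000 counts of the library (CPM), given as mean ± SD over n = 3 libraries unless stated, and log2 changes with adjusted p from edgeR.

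The first 4 principal components held 61.9%, 13.4%, 5.6% and 4.5% of the variance. KO replicate 3 stood apart in all conditions on the third component, at -43.5 to -49.8 against 0 to 20 for the other libraries. On the second component it lay between the genotypes, at 14.4, -7.3 and -13 in unstimulated, weakly and strongly stimulated cells. KO replicates 1 and 2 were there at 29.7 to 59.3 and the WT libraries at -40.9 to -13.9. The 3 libraries of KO replicate 3 held the highest levels of neutrophil and red cell transcripts. The summed level of 16 neutrophil and myeloid transcripts was 138 to 159 CPM in KO replicate 3, 40 to 82.7 CPM in the WT libraries and 0.651 to 9.95 CPM in KO replicates 1 and 2. The summed level of 4 globin transcripts was 344 to 452 CPM in KO replicate 3, 28.9 to 73.2 CPM in WT and 0.438 to 3.02 CPM in KO replicates 1 and 2. Deviations from the group mean correlated across genes between same-numbered KO libraries of different conditions, with r of 0.29 to 0.71. Between differently numbered KO libraries of different conditions r was -0.56 to 0.25. For same-numbered libraries r was 0 to 0.25 within WT and -0.19 to 0.08 between genotypes. These r values are across genes, which are not independent replicates.

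Slc23a2 (ENSMUSG00000027340.15, mm10 chromosome 2, 132052496 to 132145108) was the engineered gene. Its level was 116 ± 6.61 CPM in unstimulated WT and 79 ± 6.83 CPM in unstimulated KO, a log2 change of -0.55 ± 0.09 (SE; adjusted p = 0.00031). Under weak stimulation it was 104 ± 10.8 CPM in WT and 77.4 ± 8.85 CPM in KO, a log2 change of -0.43 ± 0.09 (adjusted p = 0.00099). Under strong stimulation it was 208 ± 5.6 CPM in WT and 84.9 ± 5.5 CPM in KO, a log2 change of -1.29 ± 0.09 (adjusted p = 4.5e-08). Over the 3 conditions the mean log2 change was -0.76 ± 0.05 (adjusted p = 5.5e-09). Strong stimulation raised Slc23a2 in WT by 0.85 on the log2 scale (adjusted p = 1.8e-07), and in KO the change was 0.10 (adjusted p = 0.31). The difference between these responses was -0.74 (adjusted p = 0.002). The counts cover all exons of the gene and the labels name no deleted exon, so these values check the deletion only in part.

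**Figure D1:**
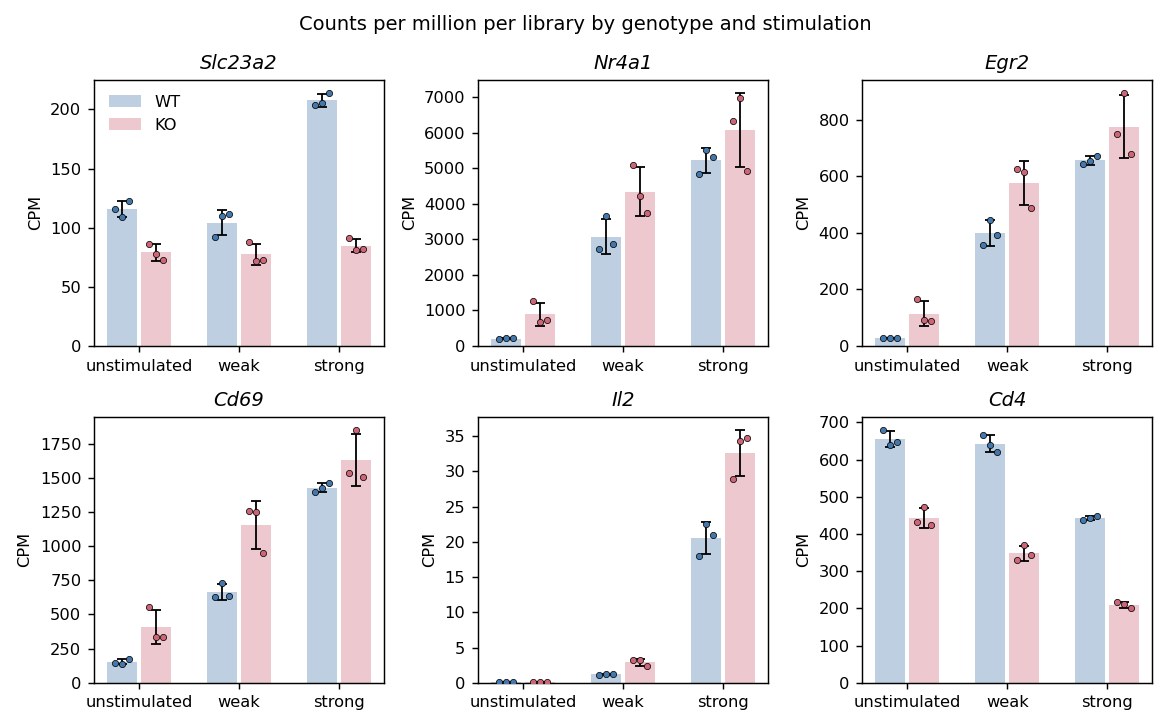
Levels in CPM (vertical axes, linear from 0) of Slc23a2, Nr4a1, Egr2, Cd69, Il2 and Cd4 in WT and KO naive CD4 T cells under the 3 conditions (horizontal axes); bars are means of 3 libraries, error bars are SD and points are libraries. Slc23a2 under strong stimulation was 208 CPM in WT and 84.9 CPM in KO, and Cd4 under strong stimulation was 443 and 210 CPM.

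The first comparison asks how unstimulated naive T cells differ with and without the ascorbate transporter. After 3 h without stimulation 20 of 24 immediate early transcription factors were higher in KO. The list was not called with an estimated correlation (adjusted p = 0.1), a setting that called no list in any comparison, those of stimulation included. Nr4a2 (ENSMUSG00000026826.13, chromosome 2, 57106830 to 57124003), an orphan nuclear receptor of the immediate early class, was 20.5 ± 0.744 CPM in WT and 242 ± 67.9 CPM in KO. Cd69, an early activation marker that retains T cells in lymphoid tissue, rose from 154 ± 19 to 409 ± 126 CPM (log2 change 1.41 ± 0.17, adjusted p = 1.4e-05). Fos went from 32.6 ± 2.71 to 162 ± 59.4 CPM and Myc, a driver of growth, from 36.8 ± 1.44 to 163 ± 37.5 CPM. The naive-cell surface proteins Cd5 and Cd6, both dampers of T cell receptor signals, went the other way, Cd5 from 201 ± 6.38 to 95.7 ± 3.99 CPM and Cd6 from 204 ± 8.35 to 75.8 ± 7.56 CPM.

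Among the lists fixed beforehand, 20 of 24 immediate early transcription factors rose in unstimulated KO and 0 fell, and 21 rose when adjusted over the list alone. Their median log2 change was 1.70 (camera adjusted p = 5.3e-20; adjusted p = 0.1 with an estimated correlation), with Nr4a2 at 3.56, Fosl2 at 2.38, Fos at 2.32 and Myc at 2.15. ERK and calcineurin feedback genes followed, with 16 of 22 up and 1 down, as well when adjusted over the list alone, at a median of 1.08 (adjusted p = 4.1e-11; adjusted p = 0.1 with an estimated correlation). Rgs1 rose by 2.26 and Cish by 1.38, and the member that fell was Rasgrp1, the exchange factor that activates RAS, at -0.85. NF-kB feedback genes had 19 of 23 up and 1 down, the same counts adjusted over the list alone, and a median of 0.49 (adjusted p = 1.3e-14; adjusted p = 0.052 with an estimated correlation), with Bcl2a1d at 1.85 and Tnfaip3 at 1.42. Of 18 activation receptors and ligands 11 rose, 13 adjusted over the list alone, and 0 fell, with Tnfsf11 (RANKL) at 3.43 and Cd274 (PD-L1) at 1.22. Their median was 0.67 (adjusted p = 1e-08; adjusted p = 0.1 with an estimated correlation). Helper lineage regulators had 7 of 17 up and 1 down, 9 and 2 adjusted over the list alone, with Irf4 at 2.52 and Maf at 1.33 and a median of 0.48 (adjusted p = 0.00023; adjusted p = 0.051 with an estimated correlation). Cytokines had 8 of 25 up and 0 down, also 8 adjusted over the list alone, with Lif at 3.01 and Tnf at 1.42 and a median of 0.55 (adjusted p = 0.017; adjusted p = 0.18 with an estimated correlation). Cholesterol biosynthesis genes had 7 of 23 up and 1 down, 8 and 1 adjusted over the list alone, at a median of 0.15 (adjusted p = 0.035; adjusted p = 0.64 with an estimated correlation).

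Some markers of myeloid, CD8 and NK cells fell in unstimulated KO. Of 19 myeloid and dendritic cell markers 4 fell and 0 rose, also when adjusted over the list alone, with Csf1r, a macrophage growth factor receptor, at -2.43 and Clec7a at -2.38. Their median was -1.10 (adjusted p = 0.00057; adjusted p = 0.64 with an estimated correlation). Of 12 CD8 and NK cell markers 3 fell and 0 rose, also adjusted over the list alone, with Cd8b1 at -1.42 and a median of -0.44 (adjusted p = 0.035; adjusted p = 0.64 with an estimated correlation). The 18 B cell markers had a median of 0.02 with 0 called. The 9 erythroid and platelet markers also had 0 called, with a median of 1.56, a mean of 1.15 and a camera direction of down (adjusted p = 0.42). KO replicates 1 and 2 lay below all WT libraries in neutrophil and globin transcripts, and KO replicate 3 lay above all of them.

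Among genes that the rule allows to be named, the largest rise was Slc15a2, a proton-coupled peptide transporter (ENSMUSG00000022899.9, chromosome 16, 36750177 to 36784962), at 1.77 ± 1.63 CPM in WT and 88.2 ± 10.1 CPM in KO (log2 change 5.75 ± 0.52, adjusted p = 7.9e-07). Chst2, a sulfotransferase, rose by 3.92, Penk, which encodes proenkephalin, by 3.76, Gls2, a glutaminase, by 2.93 and Atf3 by 2.83. Ramp3 and Bend4 rose by 3.04 and 2.72. Gabrr2, a GABA receptor subunit, changed by -4.44 and Itga6, an integrin that binds laminin, by -3.02 ± 0.13. Itga6 (ENSMUSG00000027111.15, chromosome 2, 71745616 to 71858416) was 497 ± 23.6 CPM in WT and 61.2 ± 4.6 CPM in KO. Other large falls were Klhl5 at -3.29, Fbxo17 at -3.25, Igsf23 at -2.94, Pstpip2 at -2.65, Sdcbp2 at -2.59, Prg4 at -2.49 and Dapl1 at -2.45. In these named rises and falls the 3 KO libraries did not overlap the 3 WT libraries, because the rule for naming required it.

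The list of ascorbate transport and DNA methylation genes was mixed in unstimulated cells, with 5 of 17 up and 8 down, 6 and 8 adjusted over the list alone. Its median was -0.32, its mean 0.03, and the camera adjusted p was 0.42. Tet1, a methylcytosine dioxygenase, was 8.63 ± 0.994 CPM in WT and 2.83 ± 0.562 CPM in KO (log2 change -1.61 ± 0.2), and Mbd2, which binds methylated DNA, changed by -0.73. Gadd45b and Gadd45g, implicated in DNA demethylation and also stress-inducible, rose by 2.25 and 2.04. Inhibitory receptors and tolerance factors had 9 of 31 up and 6 down, 10 and 7 adjusted over the list alone (median 0.10, adjusted p = 0.29), with Tigit at 1.80, Btla at 1.46, Cd6 at -1.43 and Cd5 at -1.07. Naive state genes had 5 of 28 up and 7 down, 7 and 10 adjusted over the list alone (median -0.22, adjusted p = 0.19), with Lef1 at -0.87 and Il6ra at -0.98. Proximal T cell receptor signalling genes had 4 of 32 up and 10 down, 4 and 12 adjusted over the list alone (median -0.14, adjusted p = 0.079). Medians of the remaining lists, none of them called, were 0.33 for regulatory T cell markers, 0.11 for memory and effector markers, 0.01 for glycolysis and glucose uptake, 0.04 for hypoxia inducible factor targets and -0.05 for ribosome biogenesis. They were 0.07 for amino acid transport and folate-linked metabolism, 0.19 for the integrated stress response, -0.16 for NRF2 targets, 0.06 for JmjC and related dioxygenases and 0.08 for interferon-stimulated genes. They were 0.02 for apoptosis and p53 targets, 0.07 for the cell cycle, 0.21 for heat shock genes, -0.04 for mitochondrially encoded transcripts and 0.17 for sex-linked transcripts. The camera adjusted p of these 15 lists ran from 0.063 to 0.96. For ribosome biogenesis the camera direction was up and for B cell markers down, against the sign of the median. Mitochondrially encoded transcripts had a mean of 0.83, which includes mt-Atp6 at 0 counts in all unstimulated WT libraries.

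edgeR called 3555 genes in unstimulated cells, 1558 higher and 1997 lower in KO, of which 840 changed by 1 or more on the log2 scale (509 higher, 331 lower). Without KO replicate 1 of this condition the count was 2210. Replicates are not stated to be separate animals, so all p-values measure the spread between these samples.

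The second comparison puts KO against WT after weak stimulation. Of 28 ribosome biogenesis genes 26 were higher in KO, and of 17 amino acid genes 15 were higher and 1 lower, but these lists were not called with an estimated correlation (adjusted p = 0.38 and 0.28). Hk2 (ENSMUSG00000000628.10, chromosome 6, 82725025 to 82774454), which commits glucose to glycolysis, was 1.12 ± 0.163 CPM in WT and 9.19 ± 2.78 CPM in KO (log2 change 3.04 ± 0.19). Slc7a5, a transporter of large neutral amino acids, was 95.0 ± 17 CPM in WT and 319 ± 80.4 CPM in KO, and Gnl3, a nucleolar protein, was 110 ± 12.1 and 245 ± 67 CPM. Il2, the main T cell growth factor, was 1.22 ± 0.0748 CPM in WT and 2.91 ± 0.511 CPM in KO (log2 change 1.24 ± 0.14). Cd4 (ENSMUSG00000023274.14, chromosome 6, 124864692 to 124888221), the co-receptor of these cells, was lower, at 643 ± 23 CPM in WT and 348 ± 21 CPM in KO (log2 change -0.89 ± 0.06).

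Of 28 ribosome biogenesis genes 26 rose and 0 fell, and all 28 rose when adjusted over the list alone. Their median was 0.75 (adjusted p = 4.6e-12; adjusted p = 0.38 with an estimated correlation), with Gnl3 at 1.16 and Nop58 at 0.95. Amino acid transport and folate-linked metabolism genes had 15 of 17 up and 1 down, also adjusted over the list alone, with Psat1, of serine synthesis, at 1.84, Slc7a5 at 1.75 and Slc7a1 at 1.64. Their median was 0.84 (adjusted p = 1.6e-07; adjusted p = 0.28 with an estimated correlation). The integrated stress response had 12 of 17 up and 0 down, also adjusted over the list alone, with Aldh18a1 at 1.36 and Atf4 at 0.54 and a median of 0.71 (adjusted p = 0.0013; adjusted p = 0.5 with an estimated correlation). Immediate early factors had 18 of 24 up and 0 down, also adjusted over the list alone, with Fosl1 at 2.04, Nr4a2 at 1.85 and Myc at 1.36 and a median of 0.88 (adjusted p = 6.1e-07; adjusted p = 0.38 with an estimated correlation). Activation receptors and ligands had 13 of 18 up and 1 down, 14 and 2 adjusted over the list alone. Tnfsf14 rose by 2.08 and Il2ra by 1.71, while the costimulatory receptor Tnfrsf4 was at -0.64, and the median was 0.82 (adjusted p = 1.6e-05; adjusted p = 0.28 with an estimated correlation). ERK and calcineurin feedback genes had 16 of 22 up and 2 down, 16 and 3 adjusted over the list alone, with Rgs1 at 2.26, Spry1 at 2.24 and Rasgrp1 at -1.30 and a median of 0.74 (adjusted p = 7.2e-06; adjusted p = 0.37 with an estimated correlation). Cytokines had 10 of 25 up and 1 down, also adjusted over the list alone, with Areg at 3.07 and Ccl4 at 2.14 and a median of 0.92 (adjusted p = 0.0045; adjusted p = 0.28 with an estimated correlation).

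Helper lineage regulators under weak stimulation had 10 of 17 up and 1 down, 11 and 1 adjusted over the list alone, with Irf4 at 1.93 and the CD4 lineage factor Zbtb7b at -0.89. Their median was 0.69 (adjusted p = 0.0018; adjusted p = 0.14 with an estimated correlation). Inhibitory receptors and tolerance factors had 15 of 31 up and 4 down, also adjusted over the list alone, with Cd160 at 2.13, Tigit at 1.57 and Dgkz, which limits diacylglycerol signals, at -0.64. Their median was 0.35 (adjusted p = 0.0045; adjusted p = 0.28 with an estimated correlation). NF-kB feedback genes had 12 of 23 up and 2 down, JmjC and related dioxygenases 12 of 28 up and 3 down and heat shock genes 7 of 12 up and 2 down. Adjusted over the list alone these counts were 12 and 2, 13 and 3, and 7 and 2. The medians were 0.29, 0.16 and 0.40 (adjusted p = 0.0013, 0.019 and 0.018; adjusted p = 0.38, 0.54 and 0.5 with an estimated correlation). Glycolysis and glucose uptake genes had 10 of 19 up and 5 down, also adjusted over the list alone, and the list was not called (median 0.22, adjusted p = 0.078). Naive state genes moved the other way, with 17 of 28 down and 5 up, also adjusted over the list alone, with Lef1 at -1.40, Il6ra at -1.22 and Foxp1 at -0.68. Their median was -0.51 (adjusted p = 0.0023; adjusted p = 0.38 with an estimated correlation). Proximal T cell receptor signalling genes had 18 of 32 down and 8 up, 19 and 8 adjusted over the list alone, with Cd247, the zeta chain of the receptor, at -1.20, and the list was not called (median -0.25, adjusted p = 0.072). Myeloid markers had 4 of 19 down and 0 up, 1 down adjusted over the list alone, and CD8 and NK cell markers 5 of 12 down and 0 up, also adjusted over the list alone. Their medians were -0.74 and -0.89 (adjusted p = 0.007 and 0.019; adjusted p = 0.58 and 0.5 with an estimated correlation). Cd8b1 was 13.7 CPM in WT and 4.06 CPM in KO.

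Slc15a2 was again high in KO, at 1.87 ± 1.63 CPM in WT and 70.9 ± 16.5 CPM in KO (log2 change 5.27 ± 0.5). Dclk1 went from 0.0736 ± 0.0256 to 6.34 ± 2.7 CPM, Penk rose by 4.48, Sema4c, a semaphorin, by 3.58 and Map2 by 3.51. Bcat1, which starts branched-chain amino acid breakdown, rose by 3.14 and Gls2 by 2.89. Gabrr2 at -4.50, Fbxo17 and Klhl5 at -3.31, Khdrbs3 at -3.26, Itga6 at -3.22, Igsf23 at -3.11, Prg4 at -2.87 and Dapl1 at -2.73 were among the largest falls. edgeR called 7102 genes, 3332 higher and 3770 lower in KO, of which 1597 changed by 1 or more on the log2 scale (923 higher, 674 lower). With KO replicate 3 as the only KO library per condition the count was 4644.

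Under strong stimulation 16 of 32 proximal T cell receptor signalling genes were lower in KO and 14 of 17 integrated stress response genes were higher, in lists not called with an estimated correlation (adjusted p = 0.078 and 0.27). Cd4 was 443 ± 4.66 CPM in WT and 210 ± 8.56 CPM in KO (log2 change -1.08 ± 0.06), and Cd247 was 198 ± 6.23 and 93.1 ± 5.65 CPM. Tet1 was 2.06 ± 0.363 CPM in WT and 0.409 ± 0.126 CPM in KO (log2 change -2.33 ± 0.25). Bhlhe40, a transcription factor induced on T cell activation, was 57.4 ± 3.23 CPM in WT and 172 ± 12.7 CPM in KO, and Il2 was 20.5 ± 2.27 and 32.6 ± 3.29 CPM. Cd69 was 1430 ± 32.4 CPM in WT and 1630 ± 192 CPM in KO.

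Proximal T cell receptor signalling genes had 16 of 32 down and 1 up, 17 and 1 adjusted over the list alone, with Grap2, an adaptor, and Cd247 at -1.09 and the kinase Txk at -0.73. Their median was -0.26 (adjusted p = 4.9e-07; adjusted p = 0.078 with an estimated correlation). Naive state genes had 17 of 28 down and 5 up, 18 and 5 adjusted over the list alone, with Dapl1 at -1.89, Lef1 and Il6ra at -1.09 and Foxp1 at -0.85. Their median was -0.43 (adjusted p = 6.4e-06; adjusted p = 0.23 with an estimated correlation). The integrated stress response had 14 of 17 up and 0 down, also adjusted over the list alone, with Eif4ebp1 at 2.19, Sesn2 at 2.10 and Cebpb at 1.66. Its median was 0.95 (adjusted p = 3.3e-07; adjusted p = 0.27 with an estimated correlation). Amino acid transport and folate-linked metabolism genes had 12 of 17 up and 1 down, 13 and 1 adjusted over the list alone. Phgdh, which opens serine synthesis, rose by 1.65, Psat1 by 1.31 and Shmt2 by 1.30, and the median was 0.54 (adjusted p = 6.4e-06; adjusted p = 0.3 with an estimated correlation). Hypoxia inducible factor targets had 9 of 22 up and 3 down, 11 and 4 adjusted over the list alone, with Vegfa at 1.89 and Egln3 at 1.10 and a median of 0.29 (adjusted p = 0.0015; adjusted p = 0.064 with an estimated correlation). Ribosome biogenesis genes had 3 of 28 up and 0 down, 0 adjusted over the list alone, at a median of 0.20 (adjusted p = 0.00079; adjusted p = 0.71 with an estimated correlation).

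Immediate early factors under strong stimulation had 12 of 24 up and 0 down, also adjusted over the list alone, with Egr4 at 1.92, Atf3 at 1.73 and Jun at 1.07. Their median was 0.38 (adjusted p = 4.9e-05; adjusted p = 0.53 with an estimated correlation). Cytokines had 10 of 25 up and 2 down, 12 and 3 adjusted over the list alone, with Areg, a ligand of the EGF receptor, at 3.13, the chemokine Xcl1 at 2.55 and Lif at 1.51. Their median was 1.01 (adjusted p = 0.00094; adjusted p = 0.078 with an estimated correlation). ERK and calcineurin feedback genes had 11 of 22 up and 2 down and helper lineage regulators 8 of 17 up and 2 down, 12 and 3 and 9 and 3 adjusted over the list alone. Maf was at 1.36 and Gata3 at 1.04, while Zbtb7b, which maintains CD4 identity, was at -1.43. The medians were 0.41 and 0.22 (adjusted p = 0.0018 and 0.0044; adjusted p = 0.53 and 0.078 with an estimated correlation). Activation receptors (6 of 18 up, 2 down, and 6 and 3 adjusted over the list alone) and NF-kB feedback genes (3 of 23 up, 4 down, also adjusted over the list alone) were not called, at medians of 0.22 and 0.09 (adjusted p = 0.15 and 0.69). Myeloid markers had 2 of 19 down and 0 up, 1 down adjusted over the list alone, at a median of -0.50 (adjusted p = 0.014; adjusted p = 0.73 with an estimated correlation). The ascorbate transport and DNA methylation list had 3 of 17 up and 6 down, 4 and 8 adjusted over the list alone, at a median of -0.28 (adjusted p = 0.29).

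Among named genes the largest rises were Slc15a2 at 4.92, Penk at 4.30, Dclk1 at 3.88, Areg at 3.13 and Map2 at 2.60. Rsad2, an interferon-induced antiviral protein, rose by 2.44 and Chac1, which degrades glutathione, by 2.41. Igsf23 at -3.51, Itga6 at -3.21, Klhl5 at -2.73, Fanci, of DNA crosslink repair, at -2.71, Ctif at -2.66, Fmnl1 at -2.52 and Epas1 at -2.43 were among the largest falls. edgeR called 3655 genes, 1528 higher and 2127 lower in KO, of which 869 changed by 1 or more on the log2 scale (345 higher, 524 lower).

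**Figure D2:**
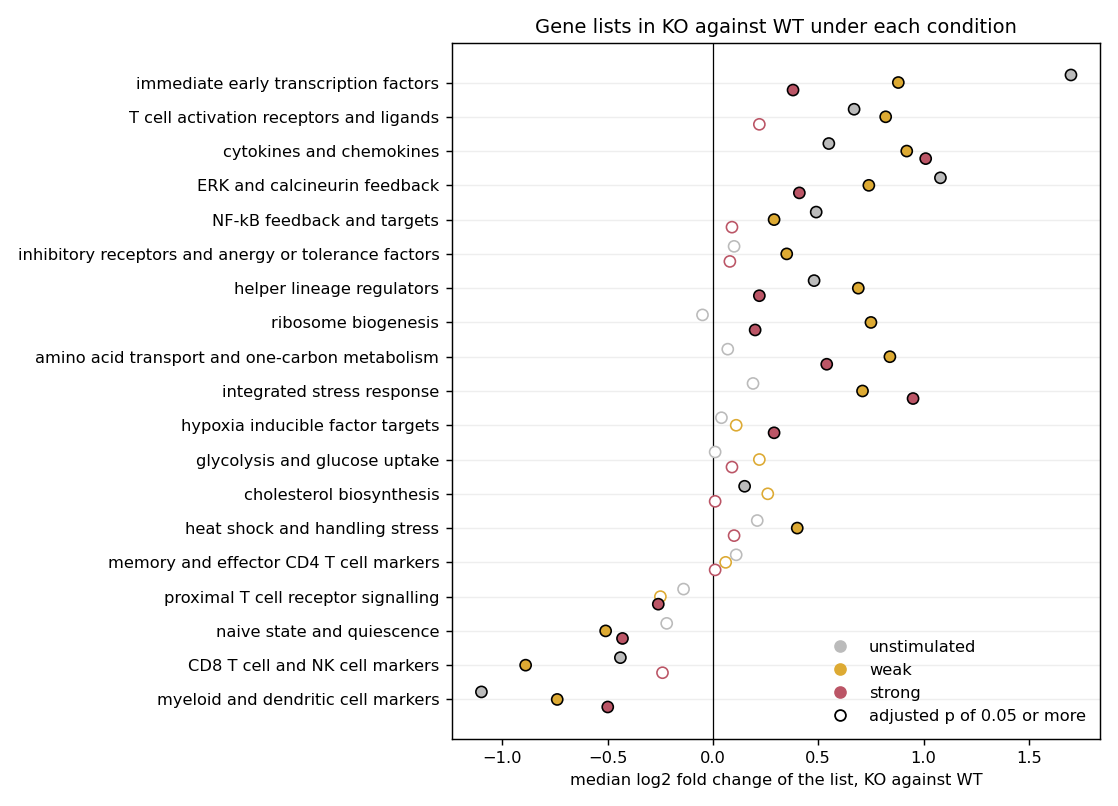
Median log2 change of KO against WT (horizontal axis) for 19 gene lists (vertical axis) under the 3 conditions (colours). Filled markers have a camera adjusted p under 0.05 at the preset correlation. The immediate early factors lie at 1.70, 0.88 and 0.38 in unstimulated, weakly and strongly stimulated cells, and ribosome biogenesis genes at -0.05, 0.75 and 0.20.

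Averaged over the 3 conditions, the genotypes differed most in genes that were high or low in KO throughout. Slc15a2 rose by 5.31, Penk by 4.18, Areg by 2.93, Map2 by 2.76, Sema4c by 2.73 and Gls2 by 2.58. Gabrr2 was at -4.41, Igsf23 at -3.19, Fbxo17 at -3.18, Itga6 at -3.15, Khdrbs3 at -3.14, Klhl5 at -3.11 and Prg4 at -2.80. Of 24 immediate early factors 21 rose and 0 fell, also adjusted over the list alone, at a median of 0.97 (adjusted p = 1.6e-11; adjusted p = 0.2 with an estimated correlation). Amino acid transport and folate-linked metabolism genes had 16 of 17 up and 1 down and ribosome biogenesis genes 24 of 28 up and 0 down, also adjusted over the list alone. Their medians were 0.61 and 0.30 (adjusted p = 6.9e-07 each; adjusted p = 0.2 and 0.47 with an estimated correlation). Proximal T cell receptor signalling genes had 21 of 32 down and 7 up and naive state genes 18 of 28 down and 5 up, also adjusted over the list alone. Their medians were -0.20 and -0.34 (adjusted p = 0.0028 and 0.0021; adjusted p = 0.3 and 0.34 with an estimated correlation). Myeloid markers had 9 of 19 down and 0 up, 8 down adjusted over the list alone, at a median of -0.79 (adjusted p = 0.00042; adjusted p = 0.51 with an estimated correlation). edgeR called 7915 genes, 3559 higher and 4356 lower, of which 1134 changed by 1 or more (551 higher, 583 lower). This fit takes the libraries of the 3 conditions as independent, though same-numbered KO libraries correlated across conditions, so its p-values may be too small. In all 3 conditions 509 genes were called higher and 908 lower in KO. Opposite calls in at least 2 conditions were made for 217 genes.

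In WT cells the stimulation comparisons ask which genes respond to the antibodies within 3 h. Egr1, an immediate early factor of the ERK pathway, went from 19.1 ± 0.685 CPM unstimulated to 1320 ± 209 CPM after weak and 1480 ± 33.6 CPM after strong stimulation. Nr4a1, a reporter of T cell receptor signal strength, went from 206 ± 6.23 to 3080 ± 494 and 5220 ± 357 CPM. Il2 was 0.134 CPM unstimulated, 1.22 ± 0.0748 CPM after weak and 20.5 ± 2.27 CPM after strong stimulation. Rflnb fell from 1030 ± 40.2 CPM to 591 CPM and 86.9 CPM. Ccr7 and S1pr1, which guide naive cells through lymph nodes, were 1070 and 1300 CPM unstimulated and 233 and 177 CPM after strong stimulation.

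After weak stimulation of WT, 18 of 24 immediate early factors rose and 0 fell, 19 adjusted over the list alone, at a median of 1.68, with Egr1 at 6.11, Nr4a1 at 3.90 and Egr2 at 3.84. Of 18 activation receptors 16 rose and 0 fell, also adjusted over the list alone, at a median of 1.73, with Cd274 at 3.18 and Slamf1 at 2.77. Cytokines had 13 of 25 up and 0 down, 14 and 1 adjusted over the list alone, at a median of 1.78, with Tnf at 4.49 and Il2 at 3.18. The camera adjusted p of these 3 lists was 6.1e-13, 1.1e-11 and 0.00038 (adjusted p = 0.34, 0.11 and 0.11 with an estimated correlation). Ribosome biogenesis genes had 23 of 28 up and 0 down, 24 and 1 adjusted over the list alone, and amino acid genes 11 of 17 up and 0 down, also adjusted over the list alone. Their medians were 0.61 and 0.79 (adjusted p = 3.7e-09 and 8.7e-06; adjusted p = 0.43 and 0.34 with an estimated correlation). Naive state genes had 18 of 28 down and 3 up, 19 and 3 adjusted over the list alone, at a median of -0.43 (adjusted p = 0.0016; adjusted p = 0.39 with an estimated correlation). Sema7a rose by 5.96, Hivep3 by 5.55, Chst2 by 5.32 and Pdcd1lg2 (PD-L2) by 4.72. Falls were smaller, with Zbed6 at -2.32, Gprin3 at -1.55 and the DNA damage kinase Atm at -1.46. edgeR called 5963 genes, 3060 higher and 2903 lower, of which 950 changed by 1 or more (786 higher, 164 lower).

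After strong stimulation of WT all 28 ribosome biogenesis genes rose, also adjusted over the list alone, at a median of 2.47, with Bysl at 3.75. Activation receptors had 16 of 18 up and 1 down, amino acid genes 15 of 17 up and 1 down and immediate early factors 21 of 24 up and 2 down, all also adjusted over the list alone. Their medians were 3.32, 2.67 and 2.14, with Cd274 at 4.87, Shmt1 at 6.62 and Egr1 at 6.27. The camera adjusted p of these 4 lists was 8.2e-14, 3.9e-07, 4.2e-06 and 1.3e-06 (adjusted p = 0.46, 0.28, 0.46 and 0.46 with an estimated correlation). Cytokines had 18 of 25 up and 2 down, 19 and 2 adjusted over the list alone, at a median of 3.08, with Il2 at 7.24 (adjusted p = 0.0034; adjusted p = 0.28 with an estimated correlation). Glycolysis genes had 13 of 19 up and 5 down, also adjusted over the list alone, at a median of 1.43, with Hk2 at 5.17 (adjusted p = 0.0089; adjusted p = 0.46 with an estimated correlation). Naive state genes had 22 of 28 down and 4 up and interferon-stimulated genes 21 of 35 down and 4 up, also adjusted over the list alone, at medians of -1.68 and -0.73 (adjusted p = 0.00015 and 0.026; adjusted p = 0.46 and 0.96 with an estimated correlation). Sema7a rose by 8.71, Npas4 by 8.70, Bcat1 by 8.36 and Hivep3 by 8.35, and Rflnb was at -3.56, Art4 at -3.44, Aqp3 at -3.28 and Fbxo32 at -3.14. edgeR called 11269 genes, 5416 higher and 5853 lower, of which 5662 changed by 1 or more (2727 higher, 2935 lower).

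Strong against weak stimulation in WT moved all 28 ribosome biogenesis genes up, also adjusted over the list alone, at a median of 1.88 (adjusted p = 4.2e-15; adjusted p = 0.4 with an estimated correlation). Activation receptors had 15 of 18 up and 1 down, also adjusted over the list alone, at a median of 1.55 (adjusted p = 1.5e-05; adjusted p = 0.4 with an estimated correlation). Bcat1 rose by 4.63, Hk2 by 4.19, Il2 by 4.07 and Tnfsf14 by 3.88, while Art4 was at -2.91, Rflnb at -2.76 and Tbxa2r at -2.63. edgeR called 10406 genes, 4923 higher and 5483 lower, of which 4062 changed by 1 or more (1828 higher, 2234 lower).

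In KO cells weak stimulation raised all 28 ribosome biogenesis genes, also adjusted over the list alone, at a median of 1.39, and 15 of 17 amino acid genes with 0 down, also adjusted over the list alone, at a median of 1.84. Their camera adjusted p was 8.6e-17 and 2e-08 (adjusted p = 0.38 and 0.28 with an estimated correlation). Activation receptors had 14 of 18 up and 2 down, 15 and 2 adjusted over the list alone, and immediate early factors 14 of 24 up and 1 down, also adjusted over the list alone, at medians of 1.56 and 0.92 (adjusted p = 1.7e-07 and 6.2e-06; adjusted p = 0.23 and 0.51 with an estimated correlation). Naive state genes had 20 of 28 down and 4 up, also adjusted over the list alone, at a median of -0.83 (adjusted p = 0.00032; adjusted p = 0.38 with an estimated correlation). Npas4 rose by 7.32, Hivep3 by 7.04, Sema7a by 6.40, Bcat1 by 6.11 and Crtam by 5.36, and Rflnb was at -1.52, Fam78a at -1.50 and Txnip, an inhibitor of glucose uptake, at -1.35. edgeR called 8071 genes, 3957 higher and 4114 lower, of which 1621 changed by 1 or more (1304 higher, 317 lower). With replicate number as a block within genotype the count was 8894.

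Strong stimulation of KO raised all 28 ribosome biogenesis genes, also adjusted over the list alone, at a median of 2.74 (adjusted p = 2.6e-13; adjusted p = 0.49 with an estimated correlation), and 16 of 17 integrated stress response genes with 1 down, also adjusted over the list alone, at 1.95 (adjusted p = 0.0021; adjusted p = 0.7 with an estimated correlation). Cytokines had 18 of 25 up and 3 down, activation receptors 14 of 18 up and 1 down and immediate early factors 16 of 24 up and 4 down, all also adjusted over the list alone. Their medians were 3.25, 2.37 and 1.33 (adjusted p = 0.0035, 3.9e-05 and 0.0021; adjusted p = 0.41, 0.41 and 0.87 with an estimated correlation). Naive state genes had 21 of 28 down and 4 up, also adjusted over the list alone, at -1.78 (adjusted p = 9.9e-05; adjusted p = 0.41 with an estimated correlation). Npas4 rose by 8.92, Xcl1 by 8.71, Tnfsf14 by 8.22 and Il2 by 7.98, and Rflnb was at -4.80, Fam78a at -4.44, Art4 at -4.31 and Gprc5b at -4.18. edgeR called 11510 genes, 5593 higher and 5917 lower, of which 6249 changed by 1 or more (2940 higher, 3309 lower), and 11927 with the block. Strong against weak stimulation in KO again raised all 28 ribosome biogenesis genes, also adjusted over the list alone, at a median of 1.26 (adjusted p = 1.1e-13; adjusted p = 0.56 with an estimated correlation), with Il2 at 3.50, Tnfsf14 at 2.92 and S1pr1 at -2.74. It called 9316 genes, 4488 higher and 4828 lower, of which 3053 changed by 1 or more (1140 higher, 1913 lower), and 9847 with the block.

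The last comparisons ask whether the response to stimulation itself differs between genotypes, as the KO change minus the WT change. For weak stimulation, 19 of 28 ribosome biogenesis genes and 9 of 17 amino acid genes had larger responses in KO, and 11 of 24 immediate early genes had lower ones. None of these lists was called with an estimated correlation. Nr4a1 went from 887 ± 327 to 4340 ± 683 CPM in KO, against 206 ± 6.23 to 3080 ± 494 CPM in WT (difference in log2 response -1.61). Egr2 went from 115 ± 44.1 to 577 CPM in KO and from 27.8 ± 0.898 to 398 CPM in WT (difference -1.51). Srxn1, which repairs oxidised peroxiredoxins, had the largest positive difference among named genes, 3.25. Crtam, a receptor induced on cytotoxic-type CD4 cells, was 4.26 CPM in WT and 13.9 CPM in KO after weak stimulation (difference 2.70).

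Of 28 ribosome biogenesis genes 19 had a larger response to weak stimulation in KO and 0 a smaller one, 27 and 0 adjusted over the list alone, at a median difference of 0.70 (adjusted p = 2e-21; adjusted p = 0.37 with an estimated correlation). Amino acid genes had 9 of 17 larger and 1 smaller, 13 and 1 adjusted over the list alone, at 0.97 (adjusted p = 1.6e-07; adjusted p = 0.37 with an estimated correlation). Immediate early factors had 11 of 24 lower and 0 higher, 13 and 1 adjusted over the list alone, at -0.69 (adjusted p = 3.4e-07; adjusted p = 0.65 with an estimated correlation), and NF-kB feedback genes 5 of 23 lower and 0 higher, 12 and 0 adjusted over the list alone, at -0.29 (adjusted p = 1.1e-05; adjusted p = 0.37 with an estimated correlation). The inhibitory receptor list was at 0.23, the naive state list at -0.35 and mitochondrially encoded transcripts at -0.21, with adjusted p = 0.0045, 0.0011 and 0.018 (adjusted p = 0.37, 0.62 and 0.91 with an estimated correlation). Their counts adjusted over the list alone were 6 higher, 2 higher with 7 lower, and 0. edgeR called 746 genes, 543 with a difference above 0 and 203 below 0, of which 180 differed by 1 or more (147 and 33). A difference above 0 is a larger rise or a smaller fall in KO. The count was 2296 with the replicate block and 1519 in DESeq2. The count was 469 without WT unstimulated replicate 3, 492 without WT weak replicate 1, 1499 without KO weak replicate 2 and 340 with KO replicate 3 alone. Of 100 relabellings of the libraries, each condition by itself, 6 including the real one called as many genes. In the other such draws the difference between genotypes itself enters the contrast, so they do not measure chance alone. The draws cannot decide the question, and chance is not excluded for this count. With whole replicate numbers relabelled together the other splits called 0 genes. These splits mix the genotypes, which lowers the count, and are too few for a share under 0.05.

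The KO minus WT difference in response to strong stimulation was below 0 in several activation lists, none of them called with an estimated correlation. A difference below 0 is a smaller rise or a larger fall in KO. Immediate early factors had 13 of 24 lower and 0 higher, 15 adjusted over the list alone, at a median of -0.99, and NF-kB feedback genes 13 of 23 lower and 0 higher, 17 adjusted over the list alone, at -0.55. Activation receptors had 8 of 18 lower and 0 higher, 10 adjusted over the list alone, at -0.61, and ERK and calcineurin feedback genes 9 of 22 lower and 0 higher, 11 adjusted over the list alone, at -0.59. Proximal T cell receptor signalling genes had 11 of 32 lower and 0 higher, 12 adjusted over the list alone, at -0.20, and Cd4, of this list, fell with strong stimulation in both genotypes. The camera adjusted p of these 5 lists was 9.2e-12, 8.4e-14, 9.1e-07, 7.2e-08 and 0.00018 (adjusted p = 0.32, 0.12, 0.28, 0.28 and 0.28 with an estimated correlation). Naive state genes were at -0.31, ribosome biogenesis at 0.24, amino acid genes at 0.27, the integrated stress response at 0.64 and NRF2 targets at 0.21, with adjusted p = 0.00053, 0.0012, 0.0084, 0.0081 and 0.043 (adjusted p = 0.47, 0.73 and, for the last 3, 0.65 with an estimated correlation). Nr4a2 was at -2.97 and Egr3 at -2.85. Pck2, a mitochondrial enzyme of gluconeogenesis, was at 2.89, with 17.6 ± 0.547 CPM in WT and 67.6 ± 50.8 CPM in KO after strong stimulation. Coq8a, of coenzyme Q synthesis, was at 1.82, with 5.99 ± 0.359 CPM in WT and 24.3 ± 2.49 CPM in KO. edgeR called 1347 genes, 616 higher and 731 lower, of which 287 differed by 1 or more (80 and 207), and 2435 with the replicate block. The count was 819 without WT unstimulated replicate 2, 860 without WT strong replicate 1 and 878 without WT strong replicate 3.

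From weak to strong stimulation, activation receptors had 9 of 18 lower and 0 higher responses in KO, 12 adjusted over the list alone, at -0.74, and ribosome biogenesis genes 11 of 28 lower and 0 higher, 20 adjusted over the list alone, at -0.57 (adjusted p = 3.7e-06 and 1.3e-08; adjusted p = 0.48 and 0.51 with an estimated correlation). Hk2 was at -1.76 and Bcat1 at -2.18. edgeR called 1724 genes, 727 higher and 997 lower, of which 312 differed by 1 or more (44 and 268), and 3080 with the replicate block. The share of higher calls was 42.2% here, 31.9% with DESeq2 size factors and 29.4% with library size alone. For strong against no stimulation it was 45.7%, and 35.4% with library size alone. The count was 614 without WT weak replicate 1, 831 without WT strong replicate 3, 1065 without WT strong replicate 1, 1113 without WT strong replicate 2 and likewise without KO weak replicate 1, and 358 with KO replicate 3 alone.

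**Figure D3:**
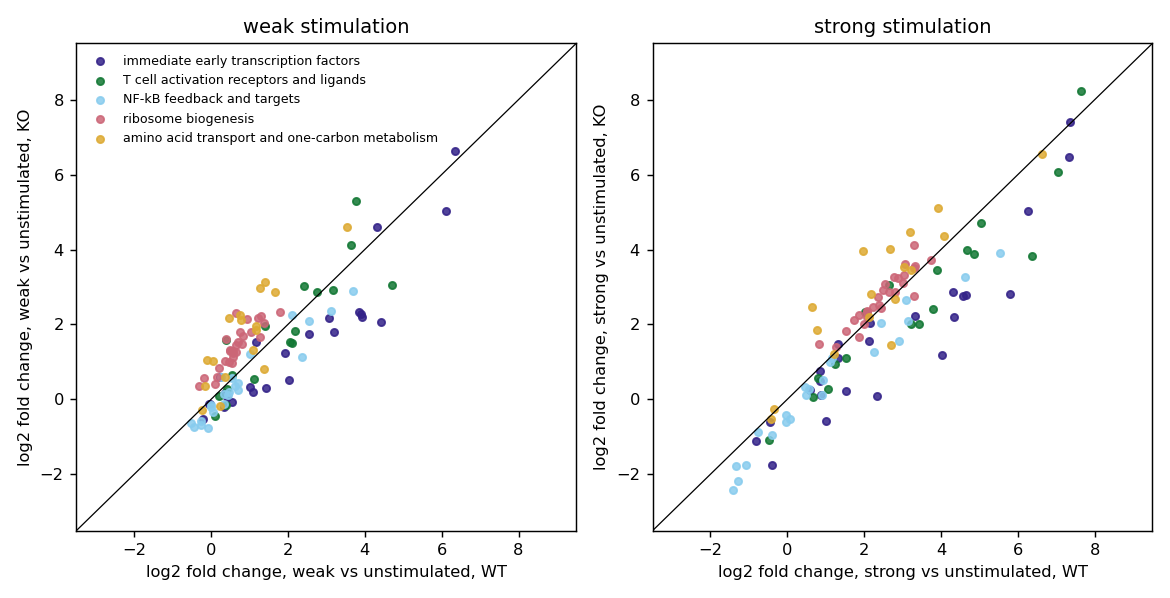
Log2 response to weak and strong stimulation against no stimulation in KO (vertical axis) against WT (horizontal axis) for the members of 5 gene lists (colours), with the line of equal response; each point is a gene. Immediate early factors lie mostly below the line under strong stimulation (median difference -0.99), and ribosome biogenesis genes mostly above it under weak stimulation (median difference 0.70).

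Genes were also grouped by their mean response over both genotypes. The 1105 genes induced by weak stimulation had a median response of 1.37 in WT and 1.82 in KO, with a median difference of 0.42 and 164 larger and 43 smaller in KO (camera p = 5.3e-09; p = 0.17 with an estimated correlation). The 2889 genes induced by strong stimulation had medians of 1.72 and 1.78, a median difference of 0.12 and 202 larger and 179 smaller in KO (p = 0.0043; p = 0.54 with an estimated correlation). The 3138 genes repressed by strong stimulation had medians of -1.55 and -1.79 and a median difference of -0.24, with 282 more and 17 less repressed in KO (p = 1.4e-12; p = 0.15 with an estimated correlation). The 1482 genes higher after strong than weak stimulation had medians of 1.67 and 1.20 and a median difference of -0.45, with 3 larger and 319 smaller in KO (p = 1.1e-19; p = 0.096 with an estimated correlation). For the 120 genes repressed by weak stimulation the median difference was 0.14 (p = 0.091; p = 0.5 with an estimated correlation), and for the 2098 lower after strong than weak stimulation it was 0.05 (p = 0.24; p = 0.82 with an estimated correlation). Across genes, which are not replicates, the slope of the KO on the WT response was 0.64, 0.79 and 0.28 for the induced sets and 0.29, 0.88 and 0.54 for the repressed sets, in the order weak, strong and strong against weak. Noise in the WT values lowers such slopes, and so does choosing the sets by a cutoff on the mean of both responses. The slopes thus do not show a weaker response in KO.

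An activation score, the mean log2 CPM of 67 activation genes per library, was 2.33 ± 0.03 in unstimulated WT and 3.30 ± 0.22 in unstimulated KO. It was 4.15 ± 0.14 and 4.99 ± 0.20 after weak stimulation and 5.20 ± 0.05 and 5.72 ± 0.05 after strong stimulation. The differences of 0.98, 0.85 and 0.52 each had an exact 2-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow.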

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

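The tests of dilution, memory cells, heat shock, fewer other cells, the 3 tests on KO replicate 3 and the splits that keep replicate numbers together were chosen only after the results they concern were seen; the other counts of splits and the test of scaling were not. For memory cells and heat shock the condition for exclusion was also changed after its outcome was seen: it first asked for a median under 0.5 and under 50% of the members up, which both lists met, and now asks for no more members up than down in place of the second part, which neither meets. The results of the next 3 paragraphs were picked out by a test of the KO minus WT difference in response, in edgeR for genes and camera for lists. Groups of 3 libraries are too small for a test of single outlying samples.

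For weak against no stimulation 746 genes differed. List medians were -0.69 for immediate early factors, -0.29 for NF-kB feedback, 0.23 for inhibitory receptors, -0.35 for naive state, 0.70 for ribosome biogenesis, 0.97 for amino acid transport and folate-linked metabolism and -0.21 for mitochondrially encoded transcripts. With an estimated correlation 0 of these lists were called (adjusted p = 0.37 to 0.91). Genes with differences above 0 were Srxn1 (3.25), Gpt2 (3.03), Crtam (2.70), Zeb2 (2.66), Nrn1 (2.33), Cdh23 (2.27), Cxcr3 (2.23), Sh3rf1 (1.95), Alcam (1.92) and Kcna3 (1.79). Differences below 0 were those of Egr3 (-2.37), Chst2 (-2.11), Pdcd1lg2 (-1.93), Plaur (-1.72), Nr4a2 (-1.71), Tnfsf11 (-1.67), Nr4a1 (-1.61), Fosl2 (-1.51), Egr2 (-1.51) and Plk3 (-1.40).

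For strong against no stimulation 1347 genes differed. List medians were -0.99 for immediate early factors, -0.61 for activation receptors, -0.59 for ERK and calcineurin feedback, -0.55 for NF-kB feedback, -0.31 for naive state, 0.24 for ribosome biogenesis, 0.27 for amino acid genes, 0.64 for the integrated stress response, 0.21 for NRF2 targets and -0.20 for proximal T cell receptor signalling. With an estimated correlation 0 of these were called (adjusted p = 0.12 to 0.73). Above 0 were Pck2 (2.89), Trib3 (2.72), Srxn1 (2.61), Eif4ebp1 (2.53), Zeb2 (2.05), Phgdh (1.98), Alcam (1.82), Coq8a (1.82), Psph (1.81) and Serpine2 (1.67). Below 0 were Spry4 (-4.94), Chst2 (-3.39), Nr4a2 (-2.97), Egr3 (-2.85), Tnfsf11 (-2.55), Pdcd1lg2 (-2.35), Syt13 (-2.31), Fmnl1 (-2.28), Fosl2 (-2.25) and Plaur (-2.21). The value of Spry4 is a fitted one that depends on the prior, since its count was 0 in all unstimulated WT libraries.

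For strong against weak stimulation 1724 genes differed. List medians were -0.26 for immediate early factors, -0.74 for activation receptors, -0.34 for ERK and calcineurin feedback, -0.24 for NF-kB feedback, -0.25 for inhibitory receptors, -0.57 for ribosome biogenesis, -0.32 for amino acid genes, 0.16 for NRF2 targets, -0.13 for proximal T cell receptor signalling and 0.25 for mitochondrially encoded transcripts, whose mean of -0.62 includes mt-Atp6, at 0 counts in all strongly stimulated KO libraries. With an estimated correlation 0 of the 10 were called (adjusted p = 0.48 to 0.73). Above 0 were Pck2 (1.81), Coq8a (1.73), Mib2 (1.52), Tec (1.30), Fndc10 (1.25), Gstt2 (1.16), Bbc3 (1.15), Cdc42ep3 (1.11) and Cdc14b (1.11). Below 0 were Zbed6 (-2.87), Dclk1 (-2.52), Bcat1 (-2.18), Kif15 (-1.93), Sema4c (-1.89), Syt13 (-1.78), Hk2 (-1.76), Kcna3 (-1.76) and Gdap10 (-1.72).

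Other splits of the libraries were counted for each comparison. Every other split of 3 against 3 libraries, and of whole replicate numbers, mixes the groups compared. The difference between the groups then counts as spread within them and lowers the count. Counts near 0 beside the real ones are thus no support. For the 9 comparisons of 3 against 3 libraries, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The highest count of another split was 0, 0 and 1 for KO against WT in unstimulated, weak and strong libraries (real counts 3555, 7102 and 3655). It was 2, 0 and 0 for WT weak against unstimulated, strong against unstimulated and strong against weak (5963, 11269 and 10406), and 4, 0 and 2 for the KO counterparts (8071, 11510 and 9316). The KO libraries were treated as paired by number, and the splits of them that part all 3 pairs gave 0. For the mean of 3 conditions 1 of 100 draws gave as many as 7915, the highest other being 169, and for the differences in response 1 of 100 gave as many as 1347 (highest other 96) and as many as 1724 (highest other 1200), but these draws relabel each condition by itself and so ignore that same-numbered KO libraries correlate across conditions. With whole replicate numbers relabelled together, 1 of 10 splits, the real one, gave as many genes for each of these and for the response to weak stimulation, the highest other being 0, and 10 splits are too few for a share under 0.05. For the difference in response to weak stimulation 6 of the 100 draws gave 746 or more, the highest other being 3511, so chance is not excluded. In the 5 others the weak labels are all real with 1 unstimulated KO label kept, or all mirrored with 2 kept. The difference between genotypes then enters the contrast with opposite signs in the 2 conditions, so these draws do not measure chance alone and cannot decide the question. The 3 further draws with such weak labels gave 0 genes, among them those that keep 2 unstimulated and 3 weak KO labels.

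Of 24 immediate early genes 20 were higher in unstimulated KO, a list not called with an estimated correlation (adjusted p = 0.1). Dilution of T cell RNA by other cells in WT would raise all T cell transcripts in KO alike, but proximal T cell receptor signalling genes had a median of -0.14 (SD of members 0.43). Fewer other cells in KO replicates 1 and 2 are argued against as the whole cause, since the unstimulated immediate early median was also 1.23 in KO replicate 3, which held the most, against 1.88 in the others (0.79 and 1.07 over the 3 conditions). Memory cells (markers at a median of 0.11, 6 of 26 up and 2 down) and a heat shock response (median 0.21, 5 of 12 up and 1 down, Hspa1a at 0.92 and Hspa1b at 0.95) cannot be told apart from the genotype, since members went both ways. The sort for naive CD4 cells should also leave out memory cells. Libraries held transcripts of other cells after it, however, so its purity cannot be assumed. A difference between genotypes in sorting or incubation stays open, untested, beside the loss of the transporter itself. Effects of Cd4Cre, which WT cells lack, cannot be told apart from that loss in this design.

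KO replicate 3 stood apart from the other KO replicates, and on the second principal component it lay between them and the WT libraries. RNA of neutrophils and red cells is a candidate source. Of the values of 20 marker transcripts 100% were highest in KO replicate 3 among KO libraries. Their sums there were 138 to 159 CPM for neutrophil and 344 to 452 CPM for globin transcripts. Of the 20 markers 8 are also on the fixed myeloid and erythroid lists. The sort for naive CD4 cells should remove such cells, but its purity cannot be assumed. Incomplete deletion is argued against by Slc23a2, which differed by -0.12 (SD 0.05) from the other KO replicates. WT libraries under these labels are argued against by the 10 largest rises, of which 100% of the values lay nearer the KO mean; over 10 rises and 10 falls it was 60% and over the falls alone 20%, and the genes were narrowed to the rises after the value over all 20 was seen, since 8 of the falls are other-cell transcripts.

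Of 24 immediate early genes 13 had lower log2 responses to strong stimulation in KO, with a list median of -0.99, in a list not called with an estimated correlation. The scaling of the libraries is argued against, since the value nearest 0 under 3 scalings was also -0.99. KO exceeded WT by a median of 1.70 unstimulated and 0.38 after strong stimulation, the values of which this difference is made, and no biological explanation was tested.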

How the results depend on the processing

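The fits with KO replicates 1 and 2 alone, with KO replicate 3 alone and with a block within KO alone were chosen only after the results were seen; the other alternatives were planned, and the cause was not tested for the changes below unless stated. Under DESeq2 size factors, library size alone, voom, DESeq2, no filter, a stricter filter and fits of 2 groups, the counts of the 10 group comparisons stayed within 1.5 times their values. Of the differences in response, that to weak stimulation (746 genes) rose to 1519 in DESeq2. With replicate number as a block within genotype the 3 differences in response (746, 1347 and 1724) gave 2296, 2435 and 3080, and with the block within KO alone 2209, 2421 and 2949. With KO replicate 3 as the only KO library, assumed to vary like the other groups, KO against WT after weak stimulation gave 4644 genes, the difference in response to weak stimulation 340 and that from weak to strong 358, with fewer samples. Ighm, an immunoglobulin chain of B cells, changed by -0.80 over the mean of 3 conditions and by 0.06 (adjusted p = 0.84) with KO replicate 3 alone, the 1 direction that reversed. Leaving out each library gave 2210 (without unstimulated KO replicate 1) to 2894 genes for KO against WT unstimulated, and 469 (without unstimulated WT replicate 3) to 1499 (without weak KO replicate 2) for the difference in response to weak stimulation, with 492 without weak WT replicate 1. For strong stimulation it gave 819 (without unstimulated WT replicate 2) to 1438, with 860 and 878 without strong WT replicates 1 and 3. From weak to strong it gave 614 (without weak WT replicate 1) to 2221, with 831, 1065 and 1113 without strong WT replicates 3, 1 and 2 and 1113 without weak KO replicate 1. The response difference of genes repressed by weak stimulation (0.14) ran from -0.33 to 0.53 and passed the test without unstimulated WT replicate 2 (0.44), weak WT replicates 2 (0.40) and 3 (0.53) or weak KO replicate 1 (0.47). That of genes lower after strong than weak stimulation (0.05) ran from -0.15 to 0.07 and passed without strong WT replicate 1 (0.05), strong KO replicate 1 (0.05), weak WT replicate 2 (0.01) or weak KO replicate 2 (0.06). With an estimated correlation the response differences of 0.42, 0.12, -0.24 and -0.45 were no longer called, since that setting widens the test alone (p = 0.17, 0.54, 0.15 and 0.096), and in all 13 comparisons 0 lists were called. For genes induced at least 2 on the log2 scale by strong stimulation the difference was 0.14 and not called (camera p = 0.25 at the preset correlation). fry, which tests each list by itself and not against other genes, called more lists: by direction 14 and 23 for KO against WT unstimulated and weak, 20 and 19 for WT weak against unstimulated and strong against weak, 20 and 17 for KO strong against unstimulated and against weak, and fewer, 4, for the difference in response to weak stimulation. Testing change in either direction it called 25, 27, 23 and 27 lists for KO against WT, 24, 27 and 27 in WT, 25, 28 and 26 in KO and 17, 21 and 20 for the differences in response. With a block on replicate number across genotypes, the myeloid list was no longer called for KO against WT after strong stimulation, and the cholesterol, proximal T cell receptor signalling and mitochondrially encoded lists became called after weak stimulation. With blocks within genotype or within KO, lists that became called were the integrated stress response for the difference in response to weak stimulation, cholesterol biosynthesis and myeloid markers for strong, and cholesterol biosynthesis, ascorbate transport and DNA methylation and heat shock for weak to strong. Cholesterol biosynthesis also became called for KO strong against unstimulated and against weak. With the block within genotype alone, so did myeloid markers for weak against unstimulated in both genotypes, the integrated stress response for WT strong against weak and sex-linked transcripts for the difference from weak to strong. Library size alone moved the median log2 change of all genes for WT strong against unstimulated from -0.05 to -0.15. Of 1472 results for named genes in a comparison, 1295 kept their direction and call in every alternative run for them, and 177 lost the call in at least 1, 1 of them (Ighm) with a reversed direction. Depth limits genes under the floor of 3 counts per library, for which no fold is given except the fitted value of Spry4.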

Other observations

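The tests of aminoacyl-tRNA synthetases were chosen only after the results were seen, so they are no independent support, and those of the stimulation axis were not. The camera p-values of this section are not adjusted over lists, so they cannot be set beside the adjusted ones of the fixed lists. Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were mostly higher in stimulated KO cells. Under strong stimulation 14 of 20 rose in KO, at a median log2 change of 0.62 (camera p = 1.4e-10; p = 0.04 with an estimated correlation). Under weak stimulation 14 rose and 1 fell, at 0.57 (p = 2.5e-08; p = 0.069 with an estimated correlation), and in unstimulated cells 1 rose and 3 fell, at -0.10. The response to stimulation was larger in KO for 15 of 20 after weak stimulation, at 0.69 (p = 0.0074 with an estimated correlation), and for 13 of 20 after strong stimulation, at 0.67 (p = 0.019 with an estimated correlation). Of 40 cytosolic ribosomal protein genes 6 rose in strongly stimulated KO, at a median of 0.19 (camera p = 1.1e-08, and p = 0.28 with an estimated correlation). In unstimulated and weakly stimulated cells 0 were called, at medians of 0.05 and -0.06.

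A further hypothesis was that KO cells of a condition lie further along the WT response to stimulation. In weakly stimulated cells 87.5% of 2727 genes that strong stimulation induced in WT were higher in KO, and 85.2% of 2935 repressed genes were lower. In the direction of the WT response 1567 and 1715 of these were called, and 73 and 112 against it (camera p = 2.6e-34 and 6.9e-28; p = 0.021 and 0.044 with an estimated correlation). These values are consistent with weakly stimulated KO cells being further along that response. In unstimulated cells the shares were 59.4% and 72% for genes that differ between strong and weak stimulation, and in strongly stimulated cells 59.2% and 61.6% for genes of the weak response, which left the hypothesis undecided there.

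Some predicted genes, chosen after their values were seen, were nearly on or off by genotype. Gm33707 (ENSMUSG00000102298.1, chromosome 3, 60769887 to 60770455) had 0 counts in all WT libraries and 235 to 733 in KO, and Gm27177 (ENSMUSG00000098975.7, chromosome 14, 69582164 to 69683286) had 74 to 225 in WT and 0 to 9 in KO. Gm9522 had 35 to 174 counts in WT and 0 to 1 in KO. Whether these differences come from loss of the transporter or from another difference between the genotypes was not tested.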
